A study of Bombyx mori with 12 samples.

How the data were processed

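The data were 2 tables of transposon entries from BmN4 cells, with 6 RNA-seq libraries and 6 libraries of small RNA bound to Flag-tagged Siwi, 2 per group. Per the labels' protocols, cells were given 500 pmol of siRNA by nucleofection, the transfection was repeated, and cells grown at 26 °C were collected after 10 days. Small RNA from the Flag-Siwi immunoprecipitates was size-selected at 22 to 35 nt, made into libraries and read for 51 nt on a MiSeq. For RNA-seq, poly-A RNA was made into stranded libraries and read in pairs on a NovaSeq. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than counting noise (chi-square per entry of 41.3 to 57.4 in RNA and 4.10 to 6.96 in small RNA), and none was counted as a duplicate.

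RNA values were RPKM, made by the authors per the file headers, and small RNA values were RPM, made by the authors per the file headers. Per the submitters' processing notes, cutadapt 3.1, Bowtie 1.3.0, SAMtools, bedtools, Trim Galore and STAR 2.7.9a were used, and their roles, the genome build, the treatment of reads with several matches, the handling of strand and the reads counted in the library total are not given in the sources used here. A read that matches several near-identical entries may therefore be divided, repeated or dropped, and entries that resemble each other are not independent. Each entry has a name with a class and a superfamily, and no coordinates. The tables list transposons only. The knockdown targets, the strand of the small RNA, and the lists of piRNA pathway genes, germ cell and somatic markers, stress genes and foreign RNA fixed beforehand were not analysed here, so the knockdowns themselves were not checked.

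Depth was recovered from the steps of the values. Every RPM value was a whole multiple of the smallest value in its library within 0.001 reads (100% of values), and RPKM values of 978 of 978 entries above 0 became whole reads within the same tolerance once a total per library and a length per entry were searched. Lengths found matched both names that state one, 6926 for Kokubaru_6926bp and 7603 for Moriya_7603bp. The library totals were 44.2 and 33.0 M reads (LucKD), 32.5 and 40.6 M (SiwiKD) and 45.2 and 36.3 M (MaelKD) in RNA. In small RNA they were 4.81 and 1.76 M reads (LucKD), 2.61 and 2.18 M (Ago3KD) and 3.02 and 1.84 M (MaelKD). A single read is thus worth less in the deeper RNA libraries, and 3 reads, taken as the floor for an entry listed at 0, stand for 0.624 to 1.70 RPM. Reads without molecular identifiers are not independent molecules, so such limits cover counting error only.

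Values were tested as log2(value + 1), as deposited, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). Entries with a mean of at least 1 over the 6 libraries of their table entered, 490 in RNA and 1004 in small RNA, and all 6 libraries shared the estimate of spread. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A fold is on the log2(value + 1) scale, which understates the change of low entries. Simulated data with known changes were tested first: for Siwi knockdown against control (486 entries) 66.1% of 2-fold and 96.9% of 4-fold changes were recovered and 1.35% of unchanged entries were called, and for Ago3 knockdown against control (1006 entries) 70.1%, 86.4% and 0.990%.

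Lists were every class and superfamily with at least 5 tested entries, known Bombyx elements, telomeric TRAS and SART elements and the rDNA elements R1Bm and R2Bm. Lists with fewer tested entries were counted only. The others were tested with camera (correlation 0.01), in 66 tests for RNA and 87 for small RNA, adjusted within each table. With an estimated correlation none of the 5 and 17 calls held. That setting called no list in any of the 66 and 87 tests. Its correlations rest on only 6 libraries in 3 groups, so a call lost there cannot tell weak lists from strong ones. A second test planned beside camera, fry, tests a list without comparing it with the other entries. No RNA list passed fry (smallest adjusted p = 0.0599). Of the small RNA lists called by camera, SINE after Ago3 knockdown (fry, adjusted p = 0.0534) and Jockey after Mael knockdown (fry, adjusted p = 0.170) did not pass. The direction of fry was not kept, so a pass need not back the camera call. Unclassified entries after Ago3 knockdown passed (fry, adjusted p = 0.0146) with a median log2 change of -0.11, while camera placed them above the rest. Named entries were, for each knockdown against control, the 10 largest rises and 10 largest falls past the threshold with a mean above the first quartile and both libraries outside both controls, the 5 entries highest in control cells and the tested known Bombyx elements, with values of the smallest p added where fewer than 5 passed in a direction. Between knockdowns they were the 5 largest each way. Other entries are said to be chosen after their values were seen. The design, lists, this rule and most alternatives were fixed before the data were examined. Alternatives were the replicate number as a block, each library left out, only the 4 libraries compared, no filter or a mean of at least 10, trimmed-mean (TMM) or median scaling, pseudocounts of 0.1 and 5, no trend and a fold of at least 2. After the data were seen, edgeR 4.0.16 (quasi-likelihood, on the recovered reads) and a collapse of 37 near-identical entries were added. Permutation tests across entries used 100000 resamples. Figures were drawn with matplotlib in Python.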

Results

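Transposon RNA and Siwi-bound small RNA were measured in BmN4 cells, a cultured line derived from the ovary of the silkworm Bombyx mori that keeps an active piRNA pathway. PIWI-interacting RNAs (piRNAs) are small RNAs that guide PIWI proteins to transposon transcripts, and Siwi and Ago3 are the PIWI proteins of the silkworm, which feed each other with cleaved RNA in the ping-pong cycle. Maelstrom (Mael) is a conserved protein of the piRNA pathway, and the series title places it in the production of the Siwi-piRNA complex. Cells received siRNA against Siwi, Ago3 or Mael, or against luciferase as the control, and were collected on day 10. Poly-A RNA was sequenced after control, Siwi and Mael knockdown, and small RNA bound to Flag-tagged Siwi after control, Ago3 and Mael knockdown, with 2 libraries per group and 12 in all. Each table lists 1716 transposon entries of the silkworm, of which 1204 carry no class. The library totals used by the authors for scaling, recovered from the steps of the values, were 32.5 to 45.2 M reads in RNA and 1.76 to 4.81 M reads in small RNA. Errors on levels below are SDs over 2 libraries, and errors on log2 changes are standard errors of the limma fit.

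The share of the libraries that fell on transposons differed between the groups. Listed transposons held 2.52% ± 0.0723 (SD, n = 2) of the RNA reads in control cells, 3.31% ± 0.263 after Siwi knockdown and 2.92% ± 0.223 after Mael knockdown. The unclassified entry with the most RNA reads in every library, BmTE_RM5-571, alone held 1.07% ± 0.178, 0.956% ± 0.0292 and 1.08% ± 0.165. Without the 10 most abundant entries the shares were 0.939% ± 0.0811, 1.38% ± 0.0642 and 1.05% ± 0.0115. LTR retrotransposons held 0.427% ± 0.0838 of the RNA reads in control cells, 0.737% ± 0.0871 with Siwi knockdown and 0.475% ± 0.0242 with Mael knockdown. Of the Siwi-bound small RNA, transposons held 43.1% ± 0.907 in control cells, 36.6% ± 0.680 after Ago3 knockdown and 49.3% ± 0.194 after Mael knockdown. LINE retrotransposons held 9.35% ± 0.422 in control cells, 4.08% ± 0.0233 with Ago3 knockdown and 12.1% ± 0.245 with Mael knockdown, and DNA transposons 5.75% ± 0.0397, 4.39% ± 0.00213 and 8.83% ± 0.0449. These sums did not follow the counts of entries after Mael knockdown, where 83 of 172 LINE entries were lower and 22 higher (40 and 45 with trimmed-mean scaling) and 36 of 71 DNA transposons lower and 13 higher (18 and 25). The single LTR element Pao filled 5.15% ± 0.0723, 8.15% ± 0.485 and 3.33% ± 0.0251 of the same libraries. For the share of all transposons, both libraries of each knockdown lay on the same side of both controls, but 2 libraries against 2 allow no exact permutation p (two-sided) below 0.333. A read may be counted under several entries, so the sums can exceed the reads themselves.

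**Figure D1:**
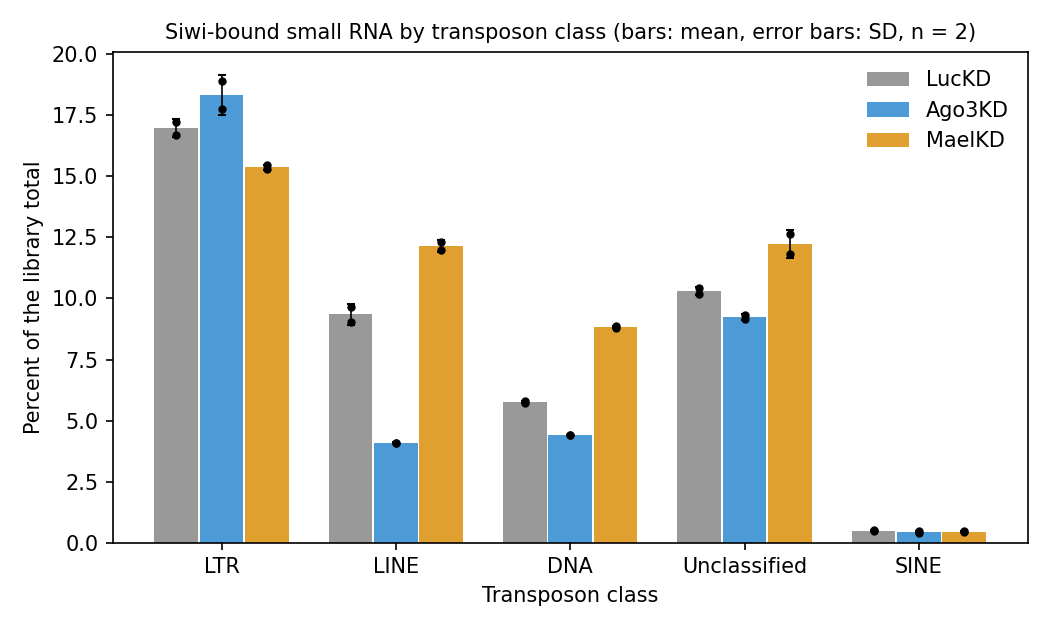
Percent of the library total that fell on each transposon class in the Siwi-bound small RNA libraries, with bars for the mean, error bars for the SD and a point for each of 2 libraries per group. LINE elements stand at 4.08% after Ago3 knockdown and 12.1% after Mael knockdown, against 9.35% in control cells, although 83 of 172 LINE entries were lower and 22 higher after Mael knockdown (40 and 45 with trimmed-mean scaling).

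The RNA comparison of Siwi knockdown with control asked which transposons change when siRNA targets the PIWI protein itself. RNA of 119 of 490 tested entries was higher and that of 15 was lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 56 rose and 2 fell by at least 2-fold on the log2(RPKM + 1) scale. The unclassified entry BmTE_RM1-644 rose most, from 12.3 ± 1.74 to 93.2 ± 8.08 RPKM (log2 change 2.83 ± 0.19, adjusted p = 8.73e-13). BmTE_RM1-432 rose from 51.8 ± 0.623 to 362 ± 45.6 RPKM and BmTE_RM1-413 from 23.7 ± 0.640 to 155 ± 22.6 RPKM. Among Gypsy LTR retrotransposons, BmTE_RM6-2827 went from 26.2 ± 2.47 to 167 ± 12.7 RPKM and Kabuki from 19.9 ± 5.68 to 83.3 ± 0.206 RPKM, 4.11-fold. The TcMar-m44 DNA transposon BmTE_RM6-2056 rose from 1.16 ± 0.0833 to 13.0 ± 0.361 RPKM.

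LTR retrotransposons had the highest median change in RNA after Siwi knockdown among the classes with at least 5 tested entries. Of 63 tested LTR entries 31 rose and 3 fell, with a median log2 change of 0.52 against 0.15 over all 490 entries. The class stood above the other entries with a preset correlation (camera, adjusted p = 0.00581). It did not with an estimated correlation (camera, adjusted p = 0.964), a setting that called no list in any comparison. Of 53 DNA transposons 21 rose and 2 fell, of 78 LINE entries 17 rose and 2 fell, and of 14 SINE entries 4 rose and none fell, although the SINE median of 0.06 turned to -0.10 with trimmed-mean scaling. Neither these 3 classes nor any superfamily passed the set test in this comparison. The 274 unclassified entries had 45 that rose and 8 that fell. Their median log2 change of 0.01, which turned to -0.15 with trimmed-mean scaling, lay below the rest (adjusted p = 0.0437, and adjusted p = 0.964 with an estimated correlation). Median and mean of that list were above 0 while its test pointed down, since it compares the list with the other entries. The falls included a Gypsy relative of Kabuki, Rikishi_Kabuki_type, from 6.18 ± 0.362 to 1.33 ± 0.415 RPKM, and the Gypsy element BmRT2, from 149 ± 66.7 to 92.5 ± 5.21 RPKM, a call lost without LucKD replicate 2 (log2 change -0.15) or without SiwiKD replicate 1 (-0.56). Of 25 known Bombyx elements, with Yamato and YAMATO_BM counted as 2, 10 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone, against 5 and 2 with trimmed-mean scaling. ChoBm1, listed as a SINE, rose from 10.6 ± 1.14 to 38.5 ± 0.932 RPKM and Gypsy-3_BM-I by 1.37 ± 0.20 on the log2 scale. None of 3 TRAS and SART elements, which insert into telomeric repeats, passed the test, and none of both rDNA elements did; R1Bm was at 56.0 ± 3.34 and 45.4 ± 7.15 RPKM, and R2Bm at 64.9 ± 8.52 and 66.5 ± 10.7 RPKM. The entry with the highest control RPKM, the SINE Bm1, was at 1453 ± 360.4 and 1123 ± 44.6 RPKM (adjusted p = 0.313). Trimmed-mean scaling moved the median of all entries from 0.15 to -0.02 and the split of calls to 90 higher and 41 lower, while 27 LTR entries rose and 4 fell. The count of calls went from 134 to 74 with no filter on low values. Single libraries moved the split: 79 entries were higher without LucKD replicate 1, and the 15 lower calls were 5 without LucKD replicate 2 and 6 without SiwiKD replicate 1.

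The RNA comparison of Mael knockdown with control gave fewer calls. RNA of 41 of 490 entries was higher and that of 13 was lower, with 18 that rose and 2 that fell by at least 2-fold. BmTE_RM1-644 rose from 12.3 ± 1.74 to 71.7 ± 10.7 RPKM (log2 change 2.45 ± 0.19, adjusted p = 3.53e-11), BmTE_RM1-432 to 236 ± 3.28 RPKM and BmTE_RM1-413 to 100.1 ± 3.29 RPKM. Of the abundant entries, BmTE_RM1-43 went from 109 ± 16.4 to 406 ± 53.3 RPKM and BmTE_RM1-42 from 199.6 ± 56.6 to 598 ± 185 RPKM. The TcMar-m44 DNA transposon BmTE_RM6-5630 rose from 3.76 ± 0.0891 to 14.4 ± 0.825 RPKM.

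By class, 23 of 274 unclassified entries rose and 9 fell in RNA after Mael knockdown. Of 63 LTR entries 10 rose and 3 fell, of 78 LINE entries 3 rose, of 53 DNA transposons 3 rose, and of 14 SINE entries 2 rose and 1 fell. Within the LTR class, 7 of 19 Pao entries rose and 1 fell, while of 28 Gypsy entries 1 rose and 2 fell. No class or superfamily passed the set test for this comparison. The Gypsy rise was Gypsy-3_BM-I, from 3.67 ± 0.563 to 8.53 ± 0.123 RPKM, and the Gypsy falls were Rikishi_Kabuki_type, to 2.09 ± 0.102 RPKM, and BmRT2, to 75.7 ± 3.90 RPKM, a call lost without LucKD replicate 2 (log2 change -0.43) or without either Mael library. Of 25 known Bombyx elements 4 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone, against 2 and 1 with trimmed-mean scaling. ChoBm1 rose to 16.5 ± 1.58 RPKM. Yamato, a Pao-type LTR element, went from 133 ± 12.3 to 203 ± 18.8 RPKM (adjusted p = 0.0406). YAMATO_BM, another of the 4 rises, had nearly the same values, 134 ± 23.7 and 207 ± 21.8 RPKM, so the count may hold 1 element under 2 names. Both of these calls were lost with trimmed-mean scaling, and those of Yamato and ChoBm1 without any 1 of the 4 libraries compared. None of the telomeric or rDNA elements passed the test. This count of 54 calls rested on single libraries: it was 18 without MaelKD replicate 2, 30 without MaelKD replicate 1 and 33 without LucKD replicate 1, and its 13 lower calls were 5 without LucKD replicate 2. It was 19 with no filter on low values and 31 with a mean of at least 10 RPKM.

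Set directly against Siwi knockdown, Mael knockdown left RNA lower for 92 of 490 entries and higher for 8. The Gypsy element BmTE_RM6-2827 stood at 33.6 ± 6.86 RPKM after Mael knockdown and at 167 ± 12.7 RPKM after Siwi knockdown (log2 difference -2.29 ± 0.19). Kabuki was at 18.4 ± 1.05 and 83.3 ± 0.206 RPKM, the Pao-type element Noguchi at 20.1 ± 3.32 and 77.5 ± 0.842 RPKM, and BmTE_RM6-2056 at 1.85 ± 0.424 and 13.0 ± 0.361 RPKM. In the other direction SINE-1_BM was at 432 ± 50.4 RPKM after Mael knockdown and 238 ± 0.409 RPKM after Siwi knockdown. Gypsy entries were lower in 14 of 28 and higher in none (camera, adjusted p = 0.00464, and adjusted p = 0.964 with an estimated correlation), and LTR entries lower in 27 and higher in 2 of 63 (adjusted p = 0.00580, and adjusted p = 0.964 with an estimated correlation). Unclassified entries tested above the rest (adjusted p = 0.0293, and adjusted p = 0.964 with an estimated correlation), although their median was -0.08, or 0.09 with trimmed-mean scaling, and 36 of 274 were lower against 5 higher. Known Bombyx elements were lower in 5 of 25, also adjusted over the list alone. With trimmed-mean scaling the split was 9 higher and 45 lower, and the median of all entries moved from -0.14 to 0.02, with 8 Gypsy entries lower. The count of 100 calls was 34, all lower, without MaelKD replicate 2, 61 without MaelKD replicate 1 and 63 without SiwiKD replicate 1, and its 8 higher calls were 13 without SiwiKD replicate 2.

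Most entries with higher RNA after Mael knockdown were also higher after Siwi knockdown, in comparisons that share their control libraries. Of the 41 entries higher after Mael knockdown, 37 were among those higher after Siwi knockdown, where independent lists would share 9.96. Lists of the same lengths from unchanged groups, simulated 100 times against the same controls and ordered by their statistic, shared 24.7 on average (17 to 31). Another 4 entries fell in both, against 0.398 in independent lists and 2.65 (0 to 6) in simulated ones. Past the threshold itself, unchanged groups shared 0 entries in each direction. Entries shared by the simulated lists had thus not passed the test in both. BmTE_RM1-43 reached 406 RPKM with Mael and 405 RPKM with Siwi knockdown, a difference that did not pass the test (adjusted p = 0.987). Of the 119 entries higher after Siwi knockdown, 69 stood above Mael knockdown in the direct test. This count depends on the scaling, since that test had 92 such calls over all entries and 45 with trimmed-mean scaling. Across the 490 entries, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.68 and Spearman's rho = 0.61. Unchanged groups gave 0.50 and 0.48, the covariance was 0.198 against a simulated 0.0262, and 72.4% of entries had the same sign in both against a simulated 66.7%. The simulated values already hold the spread between the control libraries, and the covariance beyond it was 0.172. An offset common to both controls could still be part of this excess, and the controls are too few to be divided.

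**Figure D2:**
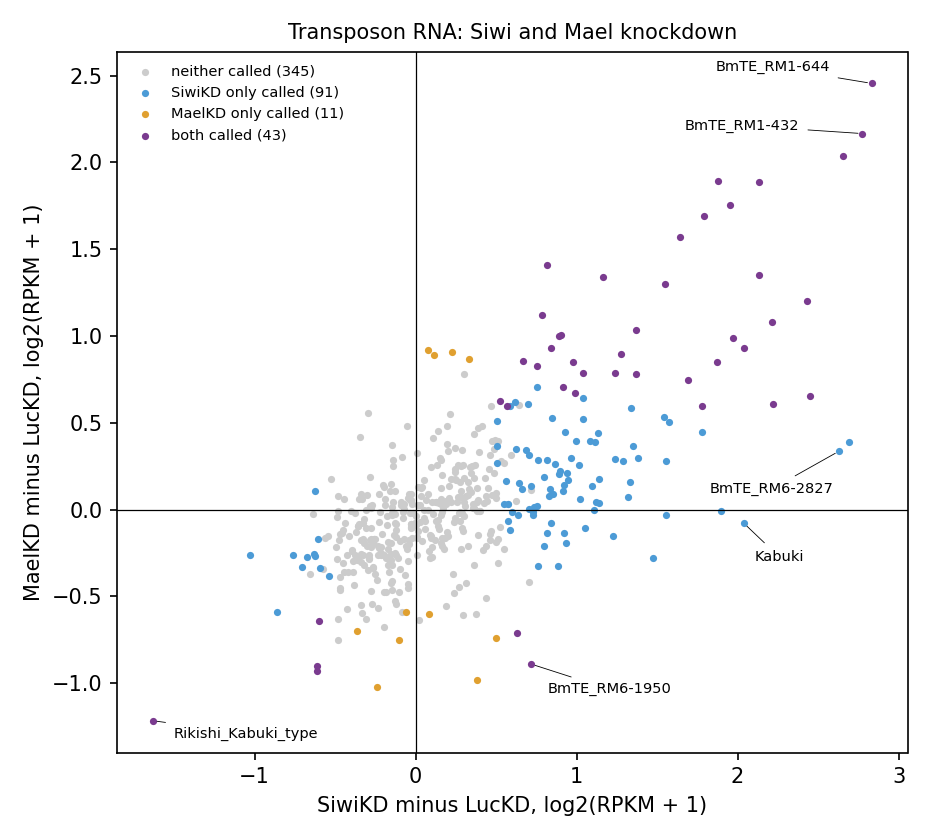
Change in transposon RNA after Siwi knockdown (x axis) against Mael knockdown (y axis), each as the difference from control in log2(RPKM + 1), with 1 point per entry and colours for the comparisons in which it was called. BmTE_RM1-644 and BmTE_RM1-432 lie far up in both, while Kabuki and BmTE_RM6-2827 lie to the right with Mael log2 changes of -0.08 and 0.34.

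The small RNA comparison of Ago3 knockdown with control asked how the Siwi-bound pool changes when siRNA targets the partner PIWI protein. Small RNA of 169 of 1004 tested entries was higher and that of 408 was lower, with 101 that rose and 197 that fell by at least 2-fold on the log2(RPM + 1) scale. Among the most abundant entries, the Jockey LINE BmTE_RM6-18 fell from 15723 ± 1212 to 4040.2 ± 8.81 RPM and BmTE_RM3-31 from 13108 ± 924 to 4353 ± 147 RPM. The LTR elements Pao and Yamato rose, from 51472 ± 723 to 81532 ± 4848 RPM and from 22213 ± 1751 to 32793 ± 1878 RPM. The unclassified entry BmTE_RM6-6914 fell 13.0-fold, from 5232 ± 142 to 402 ± 32.1 RPM (log2 change -3.70 ± 0.08, adjusted p = 2.22e-33). The Pao entry BmTE_RM6-289 rose 24.0-fold, from 91.1 ± 12.3 to 2197 ± 146 RPM (log2 change 4.58 ± 0.09, adjusted p = 4.41e-34).

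LINE and LTR entries stood below the rest after Ago3 knockdown, while 408 of all 1004 entries fell. Of 172 LINE entries 89 fell and 18 rose, with a median log2 change of -0.61 against -0.28 over all 1004 entries (camera, adjusted p = 0.0261, and adjusted p = 0.453 with an estimated correlation). Within LINEs, 13 of 19 Jockey entries fell and 1 rose (adjusted p = 0.00124, and adjusted p = 0.453 with an estimated correlation), and 12 of 17 CR1-L2 entries fell (adjusted p = 0.0261, and adjusted p = 0.453 with an estimated correlation). The RTE element RTE-1_BM fell from 413 ± 6.30 to 90.4 ± 7.18 RPM. Of 116 LTR entries 66 fell and 13 rose (adjusted p = 0.0360, and adjusted p = 0.453 with an estimated correlation), and of 54 Gypsy entries 30 fell and 4 rose (adjusted p = 0.0451, and adjusted p = 0.536 with an estimated correlation). The summed LTR share of the libraries did not follow these counts, with 17.0% ± 0.364 in control cells and 18.3% ± 0.823 after Ago3 knockdown, of which Pao held 5.15% and 8.15%. Suzuka_Kabuki_type, a Gypsy element, fell from 865 ± 4.59 to 229 ± 6.98 RPM. Of 71 DNA transposons 39 fell and 9 rose, which did not pass the set test (adjusted p = 0.160). Of 15 TcMar-Mariner DNA transposons 11 fell (adjusted p = 0.0261, and adjusted p = 0.453 with an estimated correlation), but Bmmar6 was at 1054 ± 16.0 and 1066 ± 7.16 RPM. SINE entries stood above the rest, with 6 of 20 that rose and 3 that fell (adjusted p = 0.0451, and adjusted p = 0.462 with an estimated correlation). BmSE, a tRNA-derived SINE, was at 63.7 ± 3.81 RPM in control cells and 340.0 ± 165 RPM after Ago3 knockdown, and Bm1 rose from 47.9 ± 2.83 to 119 ± 1.05 RPM. Unclassified entries tested above the rest as well (adjusted p = 0.00194, and adjusted p = 0.453 with an estimated correlation), although their median was -0.11 and 205 of 613 fell against 121 that rose.

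Of 39 known Bombyx elements 8 rose and 20 fell in Siwi-bound small RNA after Ago3 knockdown, the same counts as adjusted over the list alone. Both rDNA elements fell, R1Bm from 2367 ± 28.5 to 732 ± 14.2 RPM and R2Bm from 2181 ± 55.9 to 1280.0 ± 264 RPM. Of 5 telomeric elements 2 rose and 3 fell, among them TRAS1, from 5.31 ± 1.90 to 16.5 ± 3.89 RPM, and SART1, from 1420.2 ± 3.63 to 809 ± 84.0 RPM. Kamikaze, a Pao-type element, fell from 3190.4 ± 167 to 1881 ± 44.1 RPM. Trimmed-mean scaling moved the median of all entries from -0.28 to 0.01 and the split to 263 higher and 295 lower, with 73 LINE and 12 Jockey entries that fell; the unclassified median then became 0.15.

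**Figure D3:**
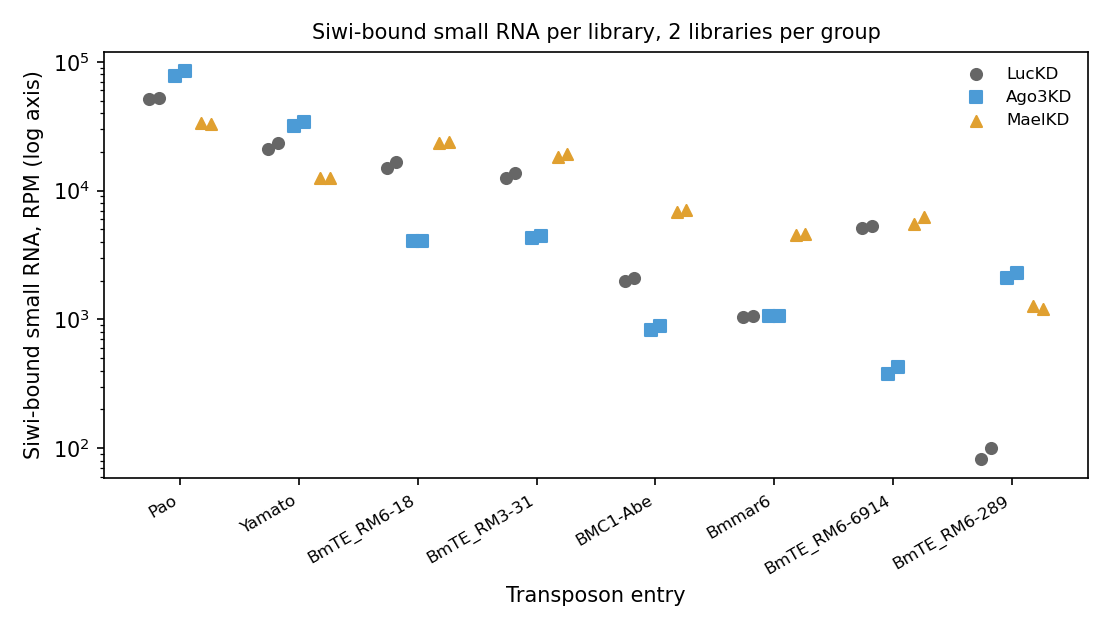
Siwi-bound small RNA in RPM (log axis) of 8 transposon entries, with 1 point for each of 2 libraries per group. The Jockey entries BmTE_RM6-18 and BmTE_RM3-31 lie below control after Ago3 knockdown and above it after Mael knockdown, and Pao and Yamato the other way round. The Pao fall after Mael knockdown did not pass the test with trimmed-mean scaling. That of YAMATO_BM, not drawn and possibly the same element as Yamato, turned above 0 with it.

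The small RNA comparison of Mael knockdown with control asked how the Siwi-bound pool changes when siRNA targets Mael. Small RNA of 118 of 1004 entries was higher and that of 446 was lower, with 36 that rose and 215 that fell by at least 2-fold. BmTE_RM6-18 rose to 23663 ± 403 RPM and BmTE_RM3-31 to 18797 ± 636 RPM, 1.51-fold and 1.44-fold above control, although reads may be shared between such Jockey entries. Yamato fell to 12543 ± 35.1 RPM and Pao to 33334 ± 251 RPM, the latter a call lost with trimmed-mean scaling (log2 change -0.04). The small RNA change of YAMATO_BM, which may be the same element as Yamato under another name, turned above 0 with that scaling. The LINE BMC1-Abe rose from 2041 ± 99.8 to 6896 ± 182 RPM and the mariner transposon Bmmar6 from 1054 ± 16.0 to 4562 ± 39.1 RPM (log2 change 2.11 ± 0.07, adjusted p = 6.50e-25).

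The direction of the average change after Mael knockdown depended on the scaling, so single entries and their rank carry most of this comparison. Under trimmed-mean scaling the median of all entries moved from -0.44 to 0.07, and the split became 261 higher and 194 lower. LINE entries fell in 83 and rose in 22 of 172, against 40 and 45 with trimmed-mean scaling, and their median of -0.51 turned to 0.01. DNA transposons fell in 36 and rose in 13 of 71, against 18 and 25, and their median of -0.45 turned to 0.11. Neither class passed the set test (camera, adjusted p = 0.933 and adjusted p = 0.933). Entries of the I superfamily of LINEs fell in 12 of 13, and in 10 of 13 with trimmed-mean scaling (camera, adjusted p = 0.00194, and adjusted p = 0.453 with an estimated correlation). BmTE_RM1-540 of this superfamily fell from 36.2 ± 8.19 to 6.74 ± 2.63 RPM. Gypsy entries fell in 38 of 54 and rose in 7, against 19 and 17 with trimmed-mean scaling (adjusted p = 0.0311, and adjusted p = 0.536 with an estimated correlation), with Matsui_Mag_type down from 352 ± 7.66 to 118 ± 0.644 RPM. LTR entries fell in 75 and rose in 19 of 116 (adjusted p = 0.0451, and adjusted p = 0.453 with an estimated correlation), and with trimmed-mean scaling their median of -0.55 turned to 0.03. Of 9 Sola DNA transposons 7 fell, and 5 with trimmed-mean scaling (adjusted p = 0.0363, and adjusted p = 0.536 with an estimated correlation). BmTE_RM6-5534, a TcMar-Fot1 DNA transposon, fell from 324 ± 14.9 to 68.9 ± 1.57 RPM, and BmTE_RM6-5279, a CR1-L2 LINE, from 321 ± 0.521 to 71.7 ± 9.37 RPM.

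Jockey entries stood above the rest after Mael knockdown, with 7 of 19 that rose and 5 that fell (camera, adjusted p = 0.0363, and adjusted p = 0.561 with an estimated correlation). Their median log2 change was 0.12 and their mean -0.07, and with trimmed-mean scaling 9 rose and 1 fell. TcMar-Tc1 DNA transposons rose in 2 of 5 (adjusted p = 0.0360, and adjusted p = 0.453 with an estimated correlation), BmTE_RM6-54 from 1151 ± 42.5 to 4759 ± 17.0 RPM. BmTE_RM6-54, Bmmar6 and the unclassified BmTE_RM5-3344 (4608 ± 41.6 RPM after Mael knockdown) had nearly the same RPM in each group, and the same reads may be counted under all of them. BmTE_RM6-289 rose 13.5-fold to 1238 ± 45.7 RPM. Its RNA was 2.13 ± 0.550 RPKM in control cells and 3.04 ± 0.0589 RPKM after Mael knockdown (adjusted p = 0.434; this entry's RNA was looked up after its small RNA values were seen). Of 39 known Bombyx elements 6 rose and 24 fell, the same counts as adjusted over the list alone, against 17 and 9 with trimmed-mean scaling. Of 5 telomeric elements 4 fell, and 2 with trimmed-mean scaling, among them SART1 to 742 ± 3.17 RPM. Of both rDNA elements R2Bm was at 2234 ± 382 RPM and R1Bm fell to 1851 ± 32.3 RPM, a change that turned to 0.23 on the log2 scale with trimmed-mean scaling.

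Mael and Ago3 knockdown differed for 526 of 1004 entries in Siwi-bound small RNA, with 208 higher and 318 lower after Mael knockdown. The W chromosome marker entry W-Sakura stood at 1203 ± 28.9 RPM after Mael knockdown and 62.2 ± 0.881 RPM after Ago3 knockdown (log2 difference 4.25 ± 0.10), and BmTE_RM6-6914 at 5869 ± 469 and 402 ± 32.1 RPM. Jockey entries were higher in 11 of 19 and lower in 2 (camera, adjusted p = 1.20e-04, and adjusted p = 0.453 with an estimated correlation). TcMar-Mariner entries were higher in 10 of 15 (adjusted p = 2.31e-04, and adjusted p = 0.453 with an estimated correlation) and TcMar-Tc1 entries in 4 of 5 (adjusted p = 0.0413, and adjusted p = 0.453 with an estimated correlation). Both rDNA elements were higher, 10 of 39 known Bombyx elements were higher and 17 lower (12 and 11 with trimmed-mean scaling), and 2 of 5 telomeric elements were lower. With trimmed-mean scaling the split was 264 higher and 204 lower, and 11 Jockey entries were higher and none lower.

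Calls of Siwi-bound small RNA were set side by side for both knockdowns, which share their control libraries. Of the entries lower after Mael knockdown 275 were also lower after Ago3 knockdown. Independent lists would share 181, and lists of the same lengths from unchanged groups, simulated 100 times against the same controls, shared 263 on average (242 to 287). Higher in both were 30 entries, against 19.9 in independent lists and 52.2 (41 to 63) in simulated ones. Past the threshold itself, unchanged groups shared at most 1 entry in each direction. Nearly all entries shared by the simulated lists had thus not passed the test in both. BmTE_RM6-289 was among the entries higher in both and BmTE_RM6-5534 among those lower in both. Another 63 entries were lower after Ago3 and higher after Mael knockdown, and 27 the reverse. Each also passed the direct test of the difference, which opposite calls with a shared spread bring about and which is no further support. With trimmed-mean scaling 52 of the 63 and 5 of the 27 had both calls and the difference. Across the 1004 entries, which are not independent, Pearson's r was 0.41 and Spearman's rho 0.40. Unchanged groups gave 0.51 and 0.46, which noise in the shared controls brings about by itself. Neither these values nor the simulated lists can thus tell whether the knockdowns share changes. The covariance was 0.300 against a simulated 0.0429, so the changes varied together by more than the simulated noise. The same sign in both was seen in 67.5% of entries against a simulated 66.8%. With trimmed-mean scaling 102 entries were lower and 113 higher in both, against 57.0 and 68.4 in independent lists. No unchanged groups were simulated with that scaling, so this excess cannot be read as shared change. Part of the overlap may come from the shared controls, which are too few to be divided.

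**Figure D4:**
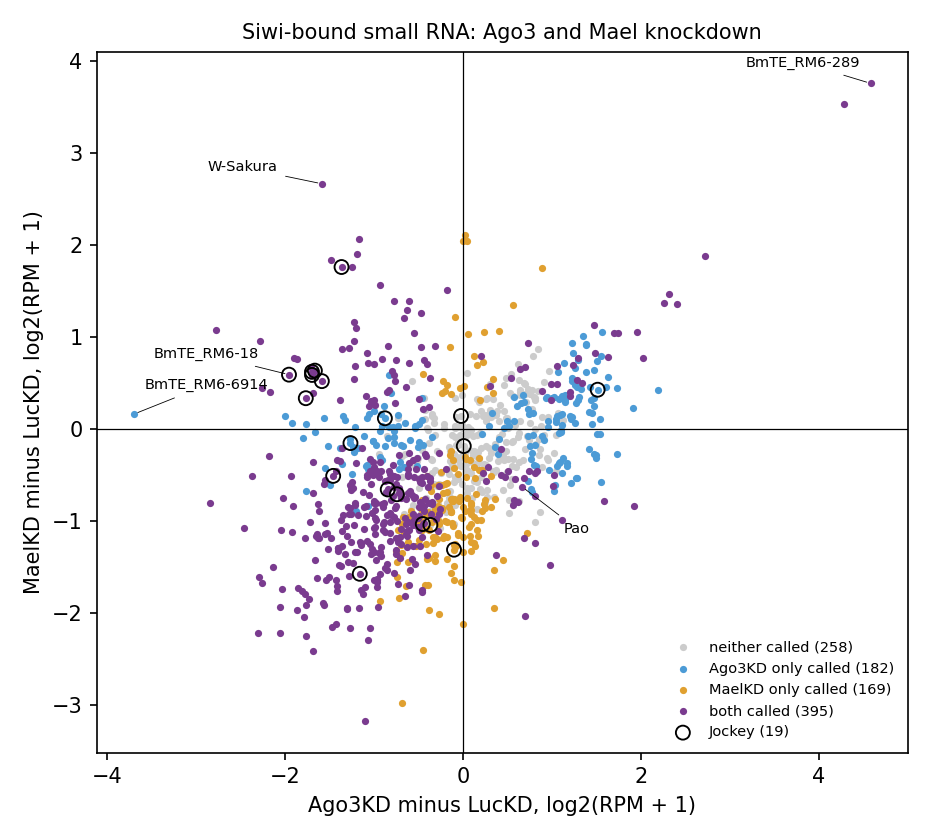
Change in Siwi-bound small RNA after Ago3 knockdown (x axis) against Mael knockdown (y axis), each as the difference from control in log2(RPM + 1), with 1 point per entry, colours for the comparisons in which it was called and circles around the 19 Jockey entries. Abundant Jockey entries such as BmTE_RM6-18 (-1.96 and 0.59) lie upper left, and BmTE_RM6-289 lies upper right.

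Small RNA and RNA changes after Mael knockdown were set side by side for the 453 entries tested in both tables, to see whether RNA rises where Siwi-bound small RNA falls. Of the 41 entries with higher RNA, 32 had less Siwi-bound small RNA, 1 had more and 8 passed no test, so 78.0% had less, against 40.5% of the other 412 entries. With trimmed-mean scaling of the small RNA these shares were 43.9% and 16.5%. Split by control RPM afterwards, with values as deposited, the shares were 90% and 54.2% in the middle of 3 groups and 77.8% and 48.9% in the highest. In the lowest, with 3 of the 41 entries, they were 0% and 20.9%. BmTE_RM1-644 had 470.0 ± 40.0 RPM in control cells and 232 ± 13.2 RPM after Mael knockdown, BmTE_RM1-43 had 808 ± 24.6 and 427 ± 23.9 RPM, and BmTE_RM6-5630 had 153 ± 13.9 and 63.0 ± 8.58 RPM. BmTE_RM1-432, with more RNA, was at 409 ± 59.3 and 417 ± 38.6 RPM (adjusted p = 0.803). BmTE_RM6-2827, with RNA lower after Mael than after Siwi knockdown, had 737 ± 38.1 RPM in control cells and 915 ± 57.8 RPM after Mael knockdown, and Kabuki, with the same RNA difference, had a small RNA log2 change of 0.04 ± 0.07 (adjusted p = 0.671). Over all 453 entries the relation was weak, with Pearson's r = -0.13 and Spearman's rho = -0.13 across entries. In 3 groups of 151 entries ordered by control RPM, Siwi knockdown raised RNA of 10, 46 and 62 entries from the lowest to the highest group, and Mael knockdown that of 3, 20 and 18. Small RNA values of the entries picked for their RNA were looked up after their RNA values were seen.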

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

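The test that counts Jockey entries with trimmed-mean scaling and the one that compares the read totals of the Siwi and Mael libraries were chosen after their results were seen, and the collapse of near-identical entries was added after the data were seen but before its result. Entries called in opposite directions in the 2 knockdowns of an assay numbered 2 in RNA and 90 in Siwi-bound small RNA. Their difference between the knockdowns passed the test in each case, which follows from the opposite calls. Given here are the entries among the largest rises or falls of a comparison, 2 and 11. In RNA, BmTE_RM6-1950 (a Pao entry) was -1.61 and TE-1_BM -1.34 on the log2 scale for Mael minus Siwi knockdown, each higher after Siwi and lower after Mael knockdown than in control cells; the Siwi rise of TE-1_BM was lost with trimmed-mean scaling (0.43 on the log2 scale, adjusted p = 0.0600). In Siwi-bound small RNA the Mael minus Ago3 differences were 4.25 for W-Sakura, 3.86 for BmTE_RM1-267, 3.32 for the CR1-Zenon entry BmTE_RM6-3153, 3.24 for the I-R1 entry BmTE_RM5-242, 3.24 for Supermite-BMC1, 3.1 for BmTE_RM5-1510 and 2.71 for the Gypsy entry BmTE_RM1-552, all higher after Mael knockdown. They were -2.75 for BmTE_RM6-7117, -2.73 for the RTE entry BmTE_RM6-1881, -2.46 for BmTE_RM4-1524 and -2.36 for BmTE_RM1-269, all higher after Ago3 knockdown. With trimmed-mean scaling the Mael falls of BmTE_RM6-7117 (log2 change -0.83) and BmTE_RM1-269 (-0.78) became -0.26 (adjusted p = 0.114) and -0.27 (adjusted p = 0.454) and lost the call, and those of BmTE_RM6-1881 and BmTE_RM4-1524 became -1.51 and -0.95. Of all 90 small RNA entries, 52 of the 63 higher after Mael knockdown and 5 of the 27 higher after Ago3 knockdown had both calls and the difference with that scaling.

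Siwi-bound small RNA of Jockey LINEs went down with Ago3 knockdown and up with Mael knockdown for 7 of 19 entries, among them BmTE_RM6-18 and BmTE_RM3-31. All 7 had both calls with trimmed-mean scaling, which moved the median of all entries up in both comparisons. Scaling by the library total thus does not account for their falls after Ago3 knockdown. For their rises after Mael knockdown the test decides nothing, since trimmed-mean scaling could only enlarge them. For the whole superfamily that test decided less: the median after Mael knockdown was 0.54 with trimmed-mean scaling, but its lower quartile was -0.17, so the entries did not go one way. After near-identical entries were collapsed, 6 of the 7 were left with both calls, so entries with matching values alone do not account for the pattern. The collapse leaves entries that may share only part of their reads, so it cannot exclude shared reads. No biological explanation was tested, and what sets these entries apart stays open.

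More transposon RNAs were higher after Siwi knockdown (119) than after Mael knockdown (41). More reads in the Siwi libraries do not account for it, since these held 32.5 and 40.6 M reads against 45.2 and 36.3 M in the Mael libraries, a ratio of means of 0.897. For the same reason reads thinned to equal totals, which left 110 and 40 (a ratio of 2.75), decide nothing. Scaling by the library total does not account for it either, since median centring left 90 and 39, a ratio of 2.31. How far each siRNA lowered its target was not analysed here, so a weaker Mael knockdown remains open, and no biological explanation was tested.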

How the results depend on the processing

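Counts of calls moved by over 1.5 times with a fold limit in both assays and, in RNA alone, with filters, single libraries and, for Mael against Siwi, scaling; scaling also moved the split of higher and lower calls. In the order Siwi against control, Mael against control and Mael against Siwi, RNA calls were 134, 54 and 100, with no filter 74, 19 and 30 (978 entries tested), with a mean of at least 10 63, 31 and 42 (156 entries tested), and with a fold of at least 2 58, 20 and 36. Small RNA calls with a fold of at least 2 were 298, 251 and 245 for Ago3 against control, Mael against control and Mael against Ago3, from 577, 564 and 526. RNA calls of Mael against Siwi were 54 with trimmed-mean scaling and 54 with median centring; the cause was not tested. Leaving out each library gave 94 to 127, 18 to 43 and 34 to 85 calls in RNA and 494 to 513, 481 to 507 and 449 to 512 in small RNA, correlations of both knockdowns of 0.599 to 0.709 (RNA) and 0.356 to 0.450 (small RNA), and -0.149 to -0.107 for small RNA with RNA. A lone library is then assumed to vary like the other groups. Median centring split the calls into 90 higher and 38 lower (RNA, Siwi against control), 10 and 44 (RNA, Mael against Siwi), 259 and 327 (Ago3 against control), 247 and 219 (small RNA, Mael against control) and 257 and 199 (Mael against Ago3). With edgeR on recovered reads, added after the data were seen, calls were 139, 53 and 108 in RNA and 578, 563 and 506 in small RNA. All set test calls, 5 in RNA and 17 in small RNA, were lost with an estimated correlation (0 and 0). That setting called no list at all, so it does not tell the lists apart. Replicate numbers did not pair the samples (correlations of same-number deviations of 0.05, 0.02 and 0.05 in RNA and -0.01, -0.05 and 0.04 in small RNA); with the replicate number as a block, calls were 148, 62 and 108 in RNA and 579, 567 and 528 in small RNA, with 4 and 18 set test calls (unclassified entries in RNA for Siwi against control left the calls, adjusted p = 0.190, and Pao entries in small RNA for Ago3 against control joined them, adjusted p = 0.0375). Correlations of both knockdowns were 0.756 (RNA) and 0.302 (small RNA) over entries with a mean of at least 10, and that of small RNA with RNA after Mael knockdown was -0.195 over 134 such entries; the cause was not tested. Ratios of the transposon share to control were 1.31 (Siwi, RNA), 0.850 (Ago3) and 1.15 (Mael, small RNA), and without the 10 most abundant entries 1.47, 0.678 and 1.07. Of 3494 alternative values of 238 named results, 3224 kept their side of the threshold, and their direction where they were called. Another 216 lost the call and 33 gained one. A further 21, called in the main test or in the alternative, changed sign, all under scaling. Sign changes of entries called in neither were not counted apart and are among the 3224. With trimmed-mean scaling, small RNA log2 changes turned to 0.045 (Gypsy-1_BM-I), 0.24 (Kimono) and 0.28 (Rikishi_Kabuki_type) after Ago3 knockdown, and after Mael knockdown to 0.18 (ChoBm1), 0.33 (Gypsy-1_BM-I), 0.072 (Gypsy-7_BM-I), 0.42 (Judo), 0.41 (Kimono), 0.35 (Mag), 0.23 (R1Bm), 0.050 (TRAS3), 0.26 (YAMATO_BM) and 0.14 (yokozuna). Median centring turned those after Mael knockdown to 0.067 (ChoBm1), 0.22 (Gypsy-1_BM-I), 0.31 (Judo), 0.30 (Kimono), 0.24 (Mag), 0.12 (R1Bm), 0.15 (YAMATO_BM) and 0.034 (yokozuna). An alternative for the antisense share was not run, since strand was not analysed here. Of simulated 1.5-fold changes, 28.1% were recovered for Siwi against control (RNA) and 53.8% for Ago3 against control (small RNA). How much of this limit is due to depth was not separated from the spread between libraries.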

Other observations

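The tests of hypotheses below were set before their results were seen; the values by groups of level and by scaling that follow them, and the entries named in the next paragraph, were chosen afterwards.

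Entries of the W chromosome, marked in the tables as RAPD markers, held 0.0269% ± 0.00215 of the Siwi-bound small RNA libraries in control cells, 0.0126% ± 8.35e-05 after Ago3 knockdown and 0.125% ± 0.00293 after Mael knockdown. This sum followed W-Sakura, which went from 189 RPM in control cells to 62.2 ± 0.881 and 1203 ± 28.9 RPM, while W-Bonsai was at 50.2 ± 3.60, 37.0 ± 5.58 and 27.8 ± 3.72 RPM. RNA of W-Sakura was 1.10 ± 0.500 RPKM in control cells and 1.08 ± 0.176 RPKM after Mael knockdown (adjusted p = 0.994). Of 7 DIRS retrotransposons 3 fell and 2 rose after Ago3 knockdown (3 and 3 with trimmed-mean scaling). BmTE_RM1-274 fell from 356 ± 22.0 to 104 ± 10.5 RPM and BmTE_RM1-288 from 331 ± 4.38 to 86.8 ± 10.4 RPM, while the low entry BmTE_RM6-1298 rose from 7.55 ± 2.15 to 16.7 ± 6.87 RPM. After Mael knockdown these 3 DIRS entries were at 369 ± 4.39, 348 ± 4.19 and 9.80 ± 1.58 RPM. BmTE_RM1-413, among the entries with the largest RNA rise in both RNA comparisons, had 1597 ± 219 RPM in control cells, 3224 ± 68.7 after Ago3 knockdown and 1127 ± 49.7 after Mael knockdown.

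A hypothesis that transposons with more Siwi-bound small RNA in control cells gain more RNA when the pathway is lowered was tested across 453 entries. Spearman's rho between control RPM and the RNA change was 0.384 for Siwi knockdown (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 5e-05 over 5 tests) and 0.178 for Mael knockdown (permutation p = 0.000160, adjusted p = 0.000400). Within 3 groups of 151 entries by RNA level rho was 0.304 to 0.425 for Siwi and 0.0958 to 0.236 for Mael knockdown. The entries are not independent, so these p-values may be too small.

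A second hypothesis was that RNA rises after Mael knockdown where Siwi-bound small RNA is lost. The median small RNA change of the 41 entries with higher RNA lay 0.45 below that of the other 412 (difference -0.447 on the log2 scale, permutation p = 0.00327, adjusted p = 0.00327 over 5 tests). The gap was seen in the middle of 3 groups by control RPM (medians -0.93 and -0.45, 20 entries with higher RNA) and in the highest (-0.45 and -0.18, 18 entries), and not in the lowest, which had 3 such entries (-0.13 and -0.30). With trimmed-mean scaling the medians were -0.16 and 0.23, so the gap is relative and whether these entries lost small RNA in absolute terms cannot be read from it. The result is consistent with a link between both changes, without showing which comes first.

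The third hypothesis, that entries with more RNA in control cells lose more Siwi-bound small RNA, found the opposite sign. Spearman's rho between control RPKM and the small RNA change was 0.167 for Ago3 knockdown (permutation p = 0.000310, adjusted p = 0.000517) and 0.165 for Mael knockdown (permutation p = 0.000430, adjusted p = 0.000537), where a value under -0.1 was predicted. Within 3 groups of 151 entries by RNA level, from lowest to highest, rho was 0.0264, 0.194 and 0.159 for Ago3 and 0.142, 0.167 and 0.0124 for Mael knockdown, so it was near 0 in 1 group for each.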
